A study of Homo sapiens with 2 samples.

How the data were processed

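PRDM1 binding was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in U266, an established human multiple myeloma cell line. There was 1 library from the PRDM1 immunoprecipitation, made with a rabbit monoclonal antibody of clone C14A4, and 1 library of input DNA that had not been immunoprecipitated. With 1 library of each kind there was no replicate, so intervals and p-values below describe counting error or the arrangement of peaks within this 1 peak list and not the spread between cultures. The series title concerns ELL3, a transcription elongation factor, in activated B lymphocytes, and the design text speaks of PRDM1 sites in 2 myeloma lines. Both libraries are labelled U266, although their growth protocol also mentions the myeloma line NCI-H929. Only these 2 libraries were analysed here.

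Reads were processed with CASAVA 1.8.2, Bowtie 0.12.7 and MACS 1.4, per the submitters' processing notes, and the peaks were called with MACS 1.4.1, per the file headers. The headers name merged alignment files for both libraries, so any sequencing runs were pooled before calling. The genome build was not given in the sources used here. Peak ends were compared with the chromosome lengths of 3 human builds, typed by hand from general knowledge: no peak passed a chromosome end of GRCh37, 53 peaks on 11 chromosomes passed one of GRCh38, and 88 peaks on 12 chromosomes passed one of NCBI36. Coordinates are therefore given as GRCh37, 1-based and as the authors deposited them.

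The deposited tables give for each peak its start, end, width and summit, the tag count, a score that is a multiple of −log10 p, a fold enrichment at the summit and a false discovery rate (FDR) in percent. The tag count is the number of ChIP tags in the peak after removal of duplicates, and is a raw count per the file headers. The score is the −log10 of the Poisson p-value of that count against the input, multiplied by 10, per the file headers. The fold is the ratio of the summit height to the local background, as deposited by the authors. The FDR percent of the authors' caller is the number of peaks called with ChIP and input swapped, divided by the number called the right way round, at the same score or above. The caller took the background as the highest of the genome mean and of input windows of 1000 and 10000 bp, with a p cutoff of 1e-05, a fragment size of 200 bp, a tag length of 51 bp and an effective genome of 2700 Mb, per the file headers. The model of the fragment size was built from regions enriched 10 to 30 times. All these values per peak are the authors' own and were used to describe, rank and filter peaks within the list.

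The complete list was deposited in 2 copies, and all 9669 peak lines were the same in both. The filtered list was recomputed from the complete list with the limits its name states, an FDR of at most 5% and at least 50 tags. The 887 peaks that passed were the 887 deposited ones. Overlaps were taken with bedtools 2.31.1 at 1 bp or more.

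The expected number of tags behind each peak was recovered from its deposited score. The tag count was multiplied by the ratio of input to ChIP tags, 1.09, and rounded down. The expected tags over the full width of the peak were then solved so that the Poisson chance of a higher count gave the deposited score. Several ways of scaling and windowing were compared, and this one was chosen after seeing which gave whole summit heights when multiplied by the deposited fold. It gave a whole number within 0.06 tags for 98.7% of 9667 peaks, where chance would give 12%. Rounding to the nearest gave 54.1% and unscaled tags gave 37.6%. The caller gave 2 peaks a score of exactly 3100. This was taken as a fixed value and not a ceiling, since 1 peak scored 3139.5. The expected tags of those 2 peaks were not recovered. For 45 of the 9667 peaks the solved background lay below 0.98 of the genome mean, which the caller's rule does not allow, so the recovery failed for them. They were kept in the medians and counts, and 1 of them is a filtered peak. Tags over expected are the scaled tags divided by the expected tags, with exact 95% Poisson intervals on the tags only. On simulated data, the background of 100% of 431 simulated peaks was recovered within 1%. Those scores were made with the same formula and rounding that the recovery solves. This checks the solving only, and not whether the caller's formula was rightly guessed.

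Peaks per chromosome were compared with the number expected from GRCh37 chromosome length, by an exact two-sided binomial test with Benjamini-Hochberg adjustment over 24 chromosomes and a threshold of 0.05. The filtered share of each chromosome's peaks was compared with that of the other chromosomes by Fisher's exact test, adjusted in the same way. In 200 simulated sets with no difference, 5% had any call, and a chromosome 19 with doubled density was called in 70% of simulated sets. Neighbouring peaks were counted between peak edges, against 10000 draws of the filtered label among the peaks of each chromosome. Neighbouring peaks are not independent, so binomial p-values over peaks are smaller than they would be over independent sites. Shares have Wilson 95% intervals, which cover counting error only. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

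The tests and the alternatives to them were fixed before the data were examined, except those named in the closing section as chosen later. The recovered backgrounds, the share of tags in peaks, the neighbour counts, the correlation over chromosomes, the 1 Mb windows and the chromosome ends were also added after the data were seen. Distances to transcription start sites, annotation of peaks, motif and 8-mer searches, 12 gene lists and the ELL, ELL2, ELL3 and PRDM1 genes had been planned for the case of an annotation of the same build. No genome or annotation of GRCh37 was used here, and coordinates were not converted, so these were not run and no gene is assigned to a peak. The rule for that case was to name the 10 strongest peaks of the filtered list by position, ranked by p, then tags, then fold. Any other peak, window or chromosome named was chosen after its values were seen, or is there because it passed a test.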

Results

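PRDM1, also called BLIMP-1, is a zinc finger repressor that drives the differentiation of B cells into antibody-secreting plasma cells. Its binding was mapped by ChIP-seq in U266, a human multiple myeloma line, which is a tumour of plasma cells. The PRDM1 library held 7954355 aligned tags, of which 7854466 were kept after duplicates were removed. The input library held 8638074, of which 8556458 were kept. Duplicates made up 1.26% of the PRDM1 tags and 0.945% of the input tags. This depth gave 2.91 PRDM1 tags and 3.17 input tags per 1 kb of effective genome. A region of 200 bp at the genome mean therefore held 0.634 input tags, so a weak site was called on few tags.

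At the authors' limits, an FDR of at most 5% and at least 50 tags, 887 regions of the U266 genome were called as PRDM1 peaks. These regions had a median width of 1531 bp and held a median of 72 tags, from 50 to 474. They covered 1.47 Mb. The median filtered peak had 10.4 times the tags expected from its input background, with an interquartile range of 7 to 14.5. Of the 885 filtered peaks with a recovered background, 791 (89.4%) held at least 5 times the expected tags, 464 (52.4%) at least 10 times and 64 (7.23%) at least 20 times. Another 20 filtered peaks lay below 3 times. The summit lay in the central 50% of the region in 94.8% of them.

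The complete list held 9669 peaks and most of them were weak. Their median width was 724 bp, with a median of 15 tags and 5.54 times the expected tags. Peaks of 9 to 11 tags made up 25.6% of the list, and 0.445% of those had an FDR of at most 5%. The share with such an FDR was 16.4% at 12 to 14 tags, 58.9% at 15 to 24 tags, 93.1% at 25 to 49 tags and 98.8% at 50 to 99 tags. The 9669 peaks held 2.98% of the PRDM1 tags (95% Wilson interval 2.97 to 2.99). The 887 filtered peaks held 1.01% (0.998 to 1.01) and the other 8782 peaks held 1.97% (1.96 to 1.98). All remaining tags lay outside peaks.

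**Figure D1:**
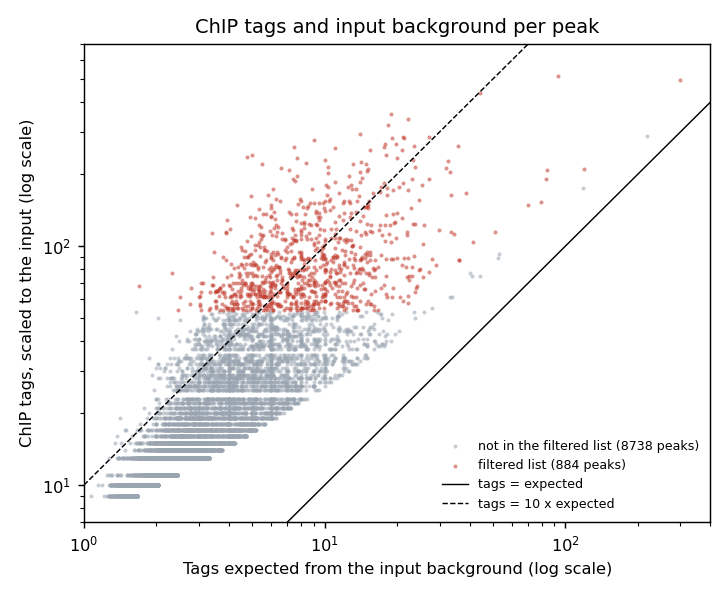
Tags per peak, scaled to the input library, against the tags expected from the input background, both on log scales, for 884 filtered peaks (red) and 8738 other peaks (grey). The lines mark equality and 10 times the expected tags. The 2 peaks with a score of exactly 3100 and 45 peaks for which the recovery failed, giving a background below the genome mean, are not drawn. The median filtered peak lies at 10.4 times the expected tags.

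The input served as the control for false calls, since the caller also called peaks in the input over PRDM1. The deposited FDR values imply 4730 peaks in that direction against 9669 for PRDM1 over input, an FDR of 48.9%. At an FDR of at most 20% the numbers were 1162 and 6083, and at 5% they were 210 and 4207. No swapped peak was implied above a score of 271.4, where 1035 PRDM1 peaks lay, and 779 of the 887 filtered peaks had an FDR of 0. The highest FDR in the filtered list was 1.35%. The FDR gave a whole number of swapped peaks within its rounding for 93.3% of peaks. This is a weak check, since the 1035 peaks with an FDR of 0 pass by construction and the tolerance widens down the list. No chance rate was computed for it.

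**Figure D2:**
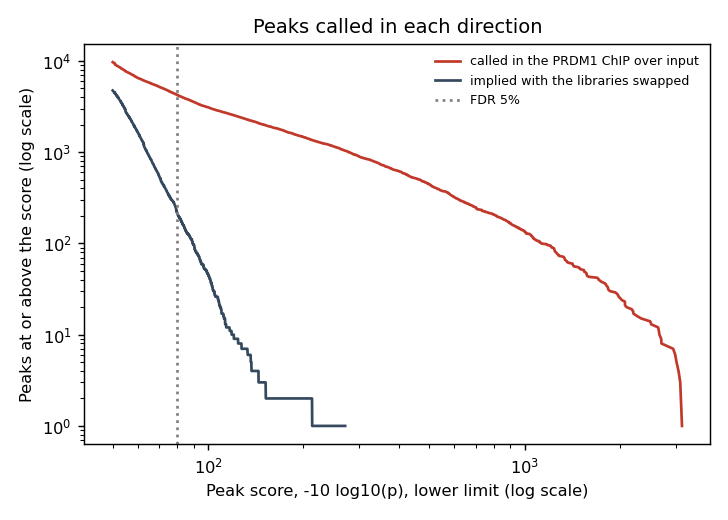
Number of peaks at or above a score (−log10 p multiplied by 10), both axes on log scales, for PRDM1 over input (red) and for the swapped direction implied by the deposited FDR (dark). At an FDR of 5% the numbers are 4207 and 210.

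The tag minimum removed most of the peaks that passed the FDR limit, 4207 of which passed it. The FDR limit removed 10 of the 897 peaks that had at least 50 tags. These 10 held 1.32 to 1.97 times the expected tags, and each had an input background of at least 5 times the genome mean. The largest was on chromosome 4 from 49108609 to 49111002, with 265 tags and 1.32 times the expected number (95% interval 1.17 to 1.48). A second lay beside it, from 49093131 to 49095377, with 161 tags and a ratio of 1.48. Others lay on chromosome 20 from 26188394 to 26190665, on chromosome 2 from 133018738 to 133020533 and on chromosome 21 from 10779916 to 10781696. The rest lay on chromosomes 9, 17, 10, 7 and 14, the largest on chromosome 9 from 126733702 to 126736633 with 86 tags. Of the filtered peaks, 22 (2.49%) had an input background as high, and 11 of those held under 3 times the expected tags.

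The peak with the highest score was on chromosome 15 from 44068203 to 44070549. It held 329 tags, 19.1 times the 18.8 expected after scaling (95% interval 17.1 to 21.2), and its fold at the summit was 82.5. ELL3, the elongation factor that the series title names, is a gene of chromosome 15. Its distance to this peak was not measured, because no annotation of this build was used here. Chromosome 7 from 138795938 to 138798133 held 421 tags at a fold of 94.1, and chromosome 9 from 37408813 to 37412234 held 302 tags at the highest fold of all filtered peaks, 196.9. The peak on chromosome 15 scored 3139.5 and the other 2 scored exactly 3100, so 3100 was not a ceiling. The scores do not order these 3 peaks by p, and the peak on chromosome 15 is not shown to have the smallest p.

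The other 7 of the 10 strongest peaks held 15.3 to 49.6 times the expected tags. The peak on chromosome 10 from 126752964 to 126754458 had the highest such ratio, 49.6 (43.5 to 56.4), with 216 tags. Chromosome 22 from 42475426 to 42476678 followed with 48.1 (42.2 to 54.6) and 222 tags. Chromosome 18 from 32439899 to 32441389 held 239 tags, 34.9 times the expected number, and chromosome 1 from 9685600 to 9687720 held 255, at 30.8 times. Chromosome 19 from 40046984 to 40050577 held 270 tags at 21 times. Chromosome 9 from 116343402 to 116344930 held 295 tags at 17.5 times. Chromosome 14 from 77427361 to 77430138 held 312 tags at 15.3 times (13.7 to 17).

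Ranking by tags gave another order, and 6 of the 10 strongest peaks by p were also among the first 10 by tags. The most tags, 474, lay on chromosome 21 from 36062338 to 36068990, the widest peak at 6653 bp, with 5.54 times the expected number. The next, with 457 tags, lay on chromosome 21 from 9825309 to 9827703. The input predicted 299.4 scaled tags there, so its ratio was 1.66 (1.52 to 1.81) despite an FDR of 0.09%. Of the 10 strongest peaks by p, 4 were also among the first 10 by fold.

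**Figure D3:**
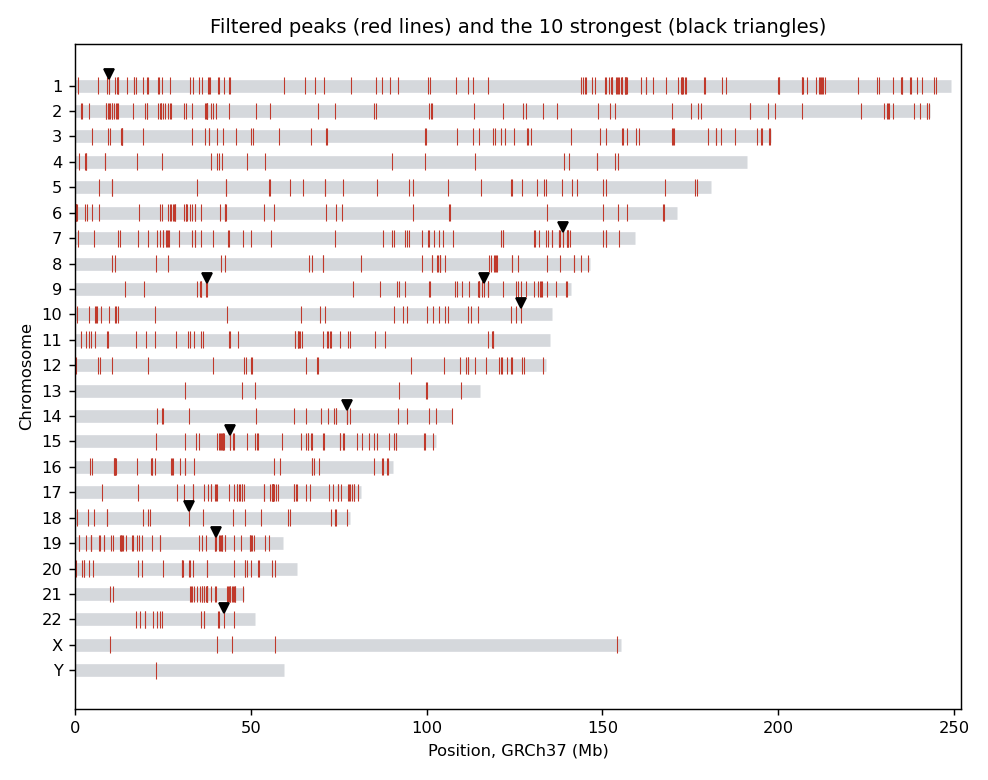
Positions of the 887 filtered peaks (red lines) along the 24 chromosomes in Mb of GRCh37, with the 10 strongest by p marked by black triangles. The 10 lie on 9 chromosomes, and 5 filtered peaks lie on chromosome X.

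Filtered peaks were unevenly spread over the chromosomes, which was examined because copy number changes and satellite repeats of a tumour line can pile up peaks. Chromosome 19 held 48 peaks, 2.83 times the number expected from its length (95% Poisson interval 2.09 to 3.76, adjusted p = 3.63e-09, exact binomial test). Chromosome 17 held 53, 2.28 times (1.71 to 2.98, exact adjusted p = 4.21e-07), and chromosome 21 held 31, 2.25 times (1.53 to 3.19, adjusted p = 0.000158). Chromosomes 1, 15 and 7 were also above, at 1.6, 1.53 and 1.38 times (exact adjusted p = 4.24e-06, 0.0148 and 0.0258). Chromosome X held 5 peaks where 44.5 were expected, a ratio of 0.112 (0.0365 to 0.262, exact adjusted p = 1.68e-12). Chromosome 13 held 7 where 33 were expected, a ratio of 0.212 (0.0853 to 0.437, exact adjusted p = 4.21e-07). Chromosomes 4, 5 and Y were below as well, at 0.438, 0.617 and 0.0588 times (exact adjusted p = 8.76e-06, 0.00867 and 4.24e-06).

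Thus 11 of 24 chromosomes departed from their length, 6 above and 5 below. In the complete list 13 did, 8 above and 5 below. Chromosomes 5 and 21 did not depart there, with ratios of 0.97 and 1.16. With a minimum of 100 tags 228 peaks remained and 4 chromosomes departed, 1 above and 3 below. Chromosome 17 passed the test above its length, at 2.84 times. Chromosomes 19, 21, 1, 15 and 7 did not pass it with so few peaks, at ratios of 2.07, 2.26, 1.53, 1.72 and 1.37, against 2.83, 2.25, 1.6, 1.53 and 1.38 with 887 peaks. With the span from the first to the last peak as length, chromosomes Y and 7 did not pass it, at 0.162 and 1.32 times. The input background moved with the number of peaks: over the 24 chromosomes, the median input background at complete-list peaks and the ratio of complete-list peaks to length had Pearson's r = 0.716 (permutation p = 0.00011) and Spearman's rho = 0.851 (permutation p = 1e-05, the smallest 100000 permutations can give). Adjusted over these 2 coefficients the p-values were 0.00011 and 2e-05. Chromosome 21 lay farthest from the median background, followed by X and Y at the same value. Pearson's r was 0.786 without 21 and Y, 0.786 without 21 and X, and 0.602 without X and Y (permutation p = 0.0045). The background is known only at called peaks, so which peaks were called may shape this relation.

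**Figure D4:**
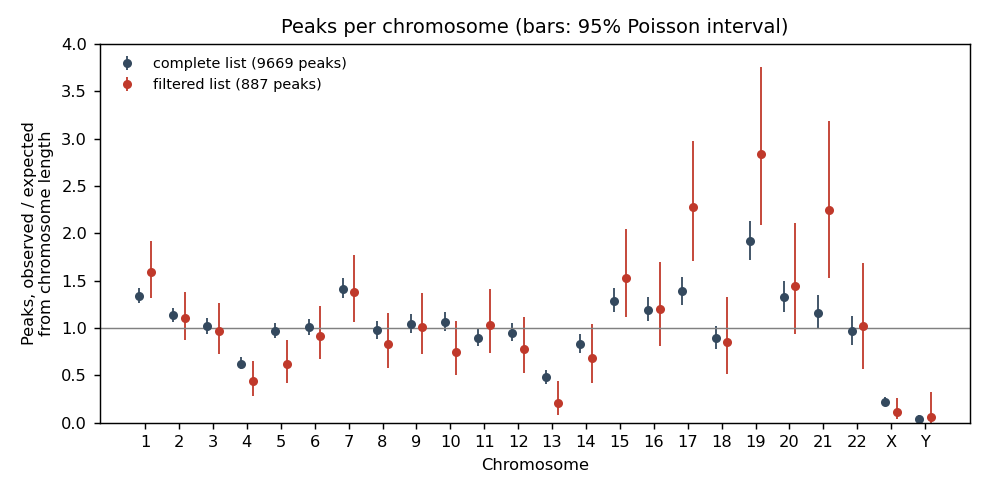
Observed peaks divided by the number expected from GRCh37 chromosome length, per chromosome, for the complete list of 9669 peaks (dark) and the filtered list of 887 (red), with 95% Poisson intervals. Chromosome 19 has the highest ratio in the filtered list, 2.83, and chromosomes X and Y have the lowest, 0.112 and 0.0588.

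Strong and weak peaks were spread differently over the chromosomes. Filtered peaks made up 9.17% of the complete list. They made up 17.7% of the peaks of chromosome 21 (adjusted p = 0.00372, Fisher's exact test), 15.1% on chromosome 17 (adjusted p = 0.00372) and 13.6% on chromosome 19 (adjusted p = 0.0373). The share was lower on chromosome 5, at 5.84% (adjusted p = 0.0373, Fisher's exact test).

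Filtered peaks lay closer to other peaks than weak ones did. Another peak of the complete list lay within 10 kb of 209 of the 887 filtered peaks (23.6%, 95% Wilson interval 20.9 to 26.5). The same held for 1381 of the 8782 other peaks (15.7%, 15 to 16.5). Drawing the filtered label at random within chromosomes gave 16.9% (14.5 to 19.3 in 95% of draws), with a two-sided permutation p of 0.0002, the smallest that 10000 draws can give.

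The 1 Mb window with the most filtered peaks was on chromosome 17 from 56000001 to 57000000. It held 7 filtered peaks where the mean was 0.287 over the genome and 0.653 over that chromosome. The exact Poisson p after multiplication by the number of windows was 7.58e-05 against the genome mean and 0.0176 against the chromosome's own. That chromosome's mean takes in its first 30 Mb, which held 3 filtered peaks against 50 on the rest. The window was not tested against the density of that rest. Windows with 5 filtered peaks began at 41000001 on chromosome 15, 11000001 on chromosome 16, 156000001 on chromosome 1, and 37000001 and 43000001 on chromosome 21 (exact Poisson p = 0.0393 each against the genome mean). Against the mean of their own chromosome none of these 5 passed, with p-values of 0.292 on chromosome 15, 0.0923 on 16, 0.353 on 1 and 1 for both on 21 (exact Poisson test, same multiplication).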

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

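The limits left out of the filter, the high-background peaks, the 100-tag chromosome counts, the span as length, both other scalings, the failed recoveries, the neighbour distances and the shares of tags at other limits were chosen after seeing the data, as were the results on tags over expected, neighbours and shares of tags themselves. The number of filtered peaks, 887, changed little at an FDR of at most 1% (886), without peaks of high input background (865) and with limits left out (856). It was 228 at 100 tags or more and 4207 with no tag minimum, by construction of the limit. All 887 overlapped the complete list at 1 bp, at 50% of the peak and at a reciprocal 50%. Of 24 chromosomes, 11 departed from their length; the number was 13 in the complete list, 11 with peaks within 10 kb counted once, 9 with the span of the peaks as length, and 4 at 100 tags or more, where there are fewer peaks. The ratios of those 11 chromosomes kept their direction under each of these settings and passed the threshold in 33 comparisons. The other 11 comparisons came from 100 tags (7: chromosomes 1, 5, 7, 15, 19, 21 and Y, at ratios of 1.53, 0.525, 1.37, 1.72, 2.07, 2.26 and 0, with fewer peaks to test), the complete list (2: 5 at 0.97 and 21 at 1.16) and the span (2: 7 at 1.32 and Y at 0.162). The median of tags over expected was 10.4, 10.3 with tags rounded to the nearest, 11.9 unscaled, 10.4 without peaks recovered below the genome mean, and 5.54 in the complete list, which holds weaker peaks. The share of tags in peaks was 2.98% in the complete list, 2.08% at an FDR of at most 5% and 1.01% in the filtered list, which has fewer peaks. The difference in neighbours between filtered and other peaks was 7.84 percentage points at 10 kb, 5.36 at 2 kb, 14.2 at 50 kb and 7.07 between centres, each past its permutation test.

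No paired analysis was possible because there was 1 library of each kind. The alternatives fixed in advance for start sites, annotation, motifs, 8-mers, gene lists, ELL loci and ranked bins were not run, since no genome or annotation of this build was used here. At 9 to 11 tags, 0.445% of peaks passed an FDR of 5%, and whether a deeper library would change this was not tested.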

Other observations

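The tests on chromosomes X and 13, the 100-tag tests and the test without X and Y were set before their results were seen; the tests sized by the input background, the blocks, both tests of adjacent windows and the chromosome ends were chosen after. No explanation by genes or by the function of PRDM1 was tested. The design has 1 cell line and no second condition. No annotation of this build was used, so peaks were not compared with the genes of each chromosome. The last peak of chromosome 11 ended at 128342576, leaving 6.66 Mb to the chromosome end without any peak of the complete list, where 18.7 were expected at the mean density of that chromosome (Poisson chance 7.89e-09, or 1.89e-07 after multiplication by 24 chromosomes). The 10 Mb before that peak held 19 peaks, 3 of them filtered. Chromosome 4 ended with 4.62 Mb free of peaks (0.0029 after the same multiplication), and the median over the 22 chromosomes other than 11 and Y was 0.302 Mb.

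Chromosomes X and 13 had few filtered peaks. If each site had only lost tags to a halved DNA copy number, a minimum of 25 tags there should give as many peaks per Mb as 50 tags elsewhere. On chromosome 13 the ratio became 0.923 (0.628 to 1.31), which met this prediction as set before. But the rise in peaks that the other chromosomes show from 25 tags would by itself give 0.549 (0.22 to 1.14). The share of its peaks from 25 tags that reached 50, 7 of 32, did not pass a test against the others (36.8%, Fisher's exact p = 0.0966). With these added comparisons a halved copy number cannot be told apart from none. On chromosome X the ratio rose from 0.105 to 0.611 (0.407 to 0.884). The rise of the other chromosomes would by itself give 0.286 (0.0926 to 0.67). Of its 29 peaks from 25 tags, 5 (17.2%) reached 50, against 36.8% of the others (Fisher's exact p = 0.0322, unadjusted). Fewer tags per site on X therefore stay open. The ratio below 1 argues against a halving as the whole cause, though a larger loss stays open. Unalignable ends are argued against for both, since with the span of the peaks as length the ratios were 0.108 (0.0351 to 0.254) for X and 0.237 (0.0952 to 0.491) for 13. The input background at the peaks was also low on X and 13. At the genome mean lay 69.4% of the peaks of X and 45.7% of those of 13, against 28.2% of all peaks. Fewer copies would lower the input, but this was not tested. The background is known only at called peaks, so these shares do not decide.

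Chromosomes 19, 17 and 21 had many filtered peaks. Counting them from 100 tags there and from 50 elsewhere, as for a doubled copy number, gave ratios of 0.541, 0.743 and 0.581. These met the prediction set before, a ratio of 1 or below. But this decides nothing, since the drop in peaks that the other chromosomes show at 100 tags would by itself take the ratios to 0.754, 0.587 and 0.579. The smallest gain that brings 1 into the interval of the ratio was 1.34, 1.3 and 1.14 times. The median input background at the peaks was set against that of the other autosomes, 0.8 tags per 200 bp. It was 1.05 times that level on chromosome 19 (bootstrap 95% interval 1.02 to 1.13) and 1 times on chromosome 17 (0.95 to 1.04). On chromosome 21 it was 1.25 times (1.2 to 1.38), and only there did it reach the gain needed. This cannot decide for or against a gain, because the background is known only at called peaks. That background is also the highest of the genome mean and of input windows of 1000 and 10000 bp. At the floor of the genome mean lay 17% of the peaks of chromosome 19, 26.7% of those of 17 and 12% of those of 21. These shares are too small for the floor to set the medians. A median of such values need not rise in proportion to copy number, so gains of whole chromosomes or of parts of them stay open. The form of this test was changed 2 times after results were seen: asking for the gain that brings the ratio itself to 1 (1.56, 1.66 and 1.4 times), against the genome mean, also left the input of 19 and 17 too low, and asking for the smallest gain against the genome mean (0.849, 0.824 and 0.723 tags per 200 bp) left them open, at a level that ordinary autosomes nearly reach.

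The input background at the peaks differed between and along chromosomes, and higher backgrounds went with more peaks. The background is known only at called peaks, and its median was 1 tag per 200 bp in filtered peaks against 0.78 in the others. Which peaks were called may therefore shape this relation and the block contrasts below, which was not tested. Chromosomes X and Y do not carry this alone, since over the 22 autosomes Spearman's rho was 0.807 (permutation p = 2e-05) and Pearson's r 0.602 (permutation p = 0.0045). In 5 blocks chosen from the 10 Mb windows because they stood out, the share of peaks at the genome background was 4.83% on chromosome 1 from 140 to 190 Mb against 29.7% on its rest, 4.89% on chromosome 2 from 0 to 40 Mb against 33.7%, 3.01% on chromosome 21 from 30 Mb against 40.5%, 64.4% on chromosome 17 below 30 Mb against 21.2%, and 77.5% on chromosome 11 from 100 Mb against 29.9%. Over all windows with at least 15 peaks, whether or not in those blocks, adjacent windows had a Spearman coefficient of 0.412 over 204 pairs (permutation p = 1e-05, one-sided, the smallest possible; mean 0.0782 with windows shuffled within chromosomes), which is consistent with segments of differing copy number as a hypothesis, while base composition along the genome, not tested here, also stays open. The test was repeated on the 4370 peaks under 15 tags that lay over 10 kb from any stronger peak, in windows with at least 10 of them. The coefficient was 0.445 over 177 pairs (permutation p = 1e-05, one-sided, mean 0.109 with shuffled windows). This argues against input raised by strong peaks within 10 kb as the only cause. The weak peaks are called sites themselves, so open chromatin at them or over wider stretches stays open.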
